A study of Homo sapiens with 18 samples.

How the data were processed

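Poly(A)-selected RNA of HepG2 cells was sequenced in 18 samples, 3 in each of 6 groups formed by 3 media and by treatment with or without sodium arsenite (0.12 mM, 2 h, then 6 h in fresh medium). The authors' processing notes name STAR for alignment and DESeq2 for the comparisons, without versions. The genome build and gene annotation are not given in the sources used here. The authors deposited 7 tables, each of 1 comparison: arsenite against untreated cells in each medium, and depleted and add-back against normal medium in untreated and in treated cells. Each table lists 60683 genes by Ensembl identifier and symbol, of which 25664 have a mean of 0.

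The log2 values are, per the file headers, the DESeq2 log2 fold change between the 2 groups of a table and its standard error. The p-values were deposited by the authors as the two-sided Wald p and its Benjamini-Hochberg adjustment after independent filtering. The score values are, per the file headers, the Wald statistic, the log2 fold change over its standard error. The signal values, per the file headers, are the mean over samples of read counts divided by DESeq2 size factors. That mean was identical in the authors' 7 deposited tables, so all 18 libraries were scaled together. No table holds a value per sample. In the symbols, 27 had been turned into dates, and names were taken by identifier from GENCODE release 29 on GRCh38, which matched 60370 identifiers.

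Folds, standard errors and adjusted p of the 7 comparisons were used as deposited, and a gene was called at an adjusted p under 0.05. In 6 genes a fold had no p. The authors' joint DESeq2 fit was rebuilt from the deposited columns to recover what the tables leave out. Genes with a single read gave the 18 size factors, and baseline means, folds and standard errors gave group means and dispersions. Over the 7 comparisons, 99.9% of the rebuilt standard errors of genes with a mean of at least 10 lay within 1% of the deposited ones. Dispersions were solved from the deposited standard errors of the arsenite comparisons, so much of this agreement is built in. In simulated data the same steps returned all 18 size factors with a largest relative error of 0. That follows from the arithmetic of single-read means, so it checks the code only. Depth per sample is thus a value rebuilt from the deposited columns, about 1.27e+07 to 3.63e+07 counts.

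Differences in the arsenite effect between media were tested as the difference of 2 deposited folds over the root of the sum of their squared standard errors, with a two-sided normal p (z test). The same z test compared add-back with depleted medium, where the shared normal-medium libraries make this standard error too large. Benjamini-Hochberg adjustment covered genes with a mean of at least 10. In simulated data the z test of the depleted minus normal difference called 10% of 100 genes changed by a log2 of 1, 80% of 100 changed by 2, and 5 unchanged genes of 14597. For add-back against depleted medium it called 3% and 77% with 0 unchanged genes, and with a standard error rebuilt for the pair 45% and 97% with 10 unchanged genes. A difference of 2-fold in 1 gene would therefore mostly be missed.

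Gene lists, 27 with 536 members of which 534 were in the tables, were written before the data were examined, as were the comparisons, the tests, the thresholds and the first set of other settings. They were tested with limma cameraPR on the Wald statistic with an inter-gene correlation of 0.01, adjusted over the lists of a comparison. Fisher's exact test compared the share of called members with that of other genes. In 200 simulated draws with 4 shifted lists each, cameraPR called 91.2% of lists shifted by 1 SD, 29.5% of lists shifted by 0.5 SD and 0.659% of unchanged lists. The draws were made at the tested correlation of 0.01, and only larger lists were shifted. The rates therefore cannot tell how often lists of more closely correlated genes are called falsely. Without values per sample, the correlation could not be estimated, and 0.05 was the alternative. Lists of 30 lymphoid and 16 fibroblast genes were written after the tables had been seen.

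Genes were named by a rule set beforehand. In each comparison these were the 8 largest rises and 8 largest falls with an adjusted p under 0.05 and a mean of at least 100, and up to 4 called members per list by smallest adjusted p, or the 2 with the highest mean where none was called. HMOX1, MT2A, HSPA1A, DDIT3, QTRT1, QTRT2 and ALKBH8 were always followed. Any other gene named was chosen after its values were seen, and is said to be.

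Of the other settings, those chosen beforehand were adjustment over all genes with a p or over those with a mean of at least 10, an adjusted p under 0.01, at least a 2-fold change, folds centred on their median and a t distribution with 4 degrees of freedom. For differences they were the route through the medium comparisons, a mean of at least 100, a t distribution with 8 degrees of freedom and 0.5 of the summed variances. Settings chosen after seeing the data were a t distribution with 12 degrees of freedom, removal of trends over GC content and transcript length, the rebuilt standard error and z scaled to its spread. Confidence intervals of medians and of rank correlations come from 10000 bootstrap resamples of genes. They treat genes as independent and do not measure the spread between samples. Permutation p come from 10000 permutations. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1.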

Results

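Messenger RNA levels were measured in HepG2 cells, a human hepatocellular carcinoma line that keeps many functions of hepatocytes, by sequencing of poly(A)-selected RNA. Cells were grown overnight in 1 of 3 media: normal growth medium, a medium with queuine-depleted serum, and the depleted medium with queuine added back. Queuine is a base taken up from diet and gut microbes. The enzyme formed by QTRT1 and QTRT2 places it at the wobble position of the tRNAs for tyrosine, histidine, asparagine and aspartate, where it is called queuosine. In each medium, cells were left untreated or exposed to 0.12 mM sodium arsenite, the dose lethal to 20% of cells, for 2 h and given fresh medium for 6 h before RNA was taken. Each of the 6 groups holds 3 samples, 18 in all. The labels do not say whether the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

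The values used are those of the authors' 7 deposited DESeq2 tables, 1 per pair of groups. They list 60683 genes with 1 mean over all 18 samples each and no value per sample. Size factors recovered from genes with a single read lay between 0.690 and 2.02, about 1.27e+07 to 3.63e+07 counts per sample. They were 0.690 to 1.06 for the arsenite libraries and 0.813 to 2.02 for the untreated ones. At the median dispersion of 0.0593, replicates of a well-expressed gene varied by 24.3%. Fold changes are log2 values ± standard error, each of 3 against 3 samples. A gene is said to have risen or fallen where its adjusted p was under 0.05. Counts at an unadjusted p under 0.05 over a whole comparison are out of 35013 genes with a p in each deposited comparison. In each difference tested here they are out of 14585. A share of 0.05 of these would be expected without any effect. Coordinates are those of GENCODE release 29 on GRCh38.

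The first question was what arsenite does to HepG2 cells in normal growth medium. Most heat shock genes and part of the targets of the oxidant-responsive factor NRF2, of the metal-binding genes and of the arsenic-handling genes rose after arsenite. Part of the genes of cholesterol synthesis, the cell cycle and endoplasmic reticulum folding fell. HSPA6, an Hsp70 chaperone that is nearly silent without stress, rose by 7.33 ± 1.35 (DESeq2 adjusted p = 6.27e-06) in the authors' deposited table. HMOX1, which degrades heme, rose by 4.95 ± 0.42 (DESeq2 adjusted p = 1.42e-28) in the authors' deposited table. HSPA1A, the main inducible Hsp70, rose by 4.24 ± 0.78 (DESeq2 adjusted p = 5.86e-06) in the authors' deposited table. CYP1A1, a cytochrome P450 induced through the aryl hydrocarbon receptor, fell by 3.28 ± 0.46 (DESeq2 adjusted p = 3.34e-10) in the authors' deposited table. In all, 956 genes rose and 753 fell, with 3901 at an unadjusted p under 0.05 in the authors' deposited table.

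HSPA6 lies on chromosome 1 at 161524540 to 161526910. Its group mean, rebuilt from the authors' deposited tables, was 35.1 normalized counts in untreated and 5641 in treated cells. HMOX1, on chromosome 22 at 35380361 to 35394214, had rebuilt means of 1706 and 52737 in these groups, from the authors' deposited tables. Other large rises were those of the secreted protease HTRA3 (5.83 ± 0.55), the small GTPase RRAD (4.55 ± 0.65) and the muscle RING-finger protein TRIM54 (4.36 ± 0.34) in the authors' deposited table. The nuclear import receptor KPNA7 (4.31 ± 0.41) and the hormone-like protein METRNL (4.21 ± 0.37) followed in the authors' deposited table, and these 5 had DESeq2 adjusted p of at most 1.15e-09. Among genes with a mean of at least 100, the next largest falls in the authors' deposited table were those of the amino acid transporter SLC6A14 (-2.81 ± 0.37), the TNF receptor family member TNFRSF19 (-2.66 ± 0.26) and the activin subunit INHBC (-2.50 ± 0.34). The FGF19 co-receptor KLB (-2.41 ± 0.37), the bile acid receptor NR1H4 (-2.41 ± 0.42) and the liver peptide gene LEAP2 (-2.39 ± 0.47) followed in the authors' deposited table. The pseudogene OR2I1P, whose reads are uncertain, was at -2.41 ± 0.36 in the authors' deposited table, and these 7 genes had DESeq2 adjusted p of at most 3.62e-05.

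**Figure D1:**
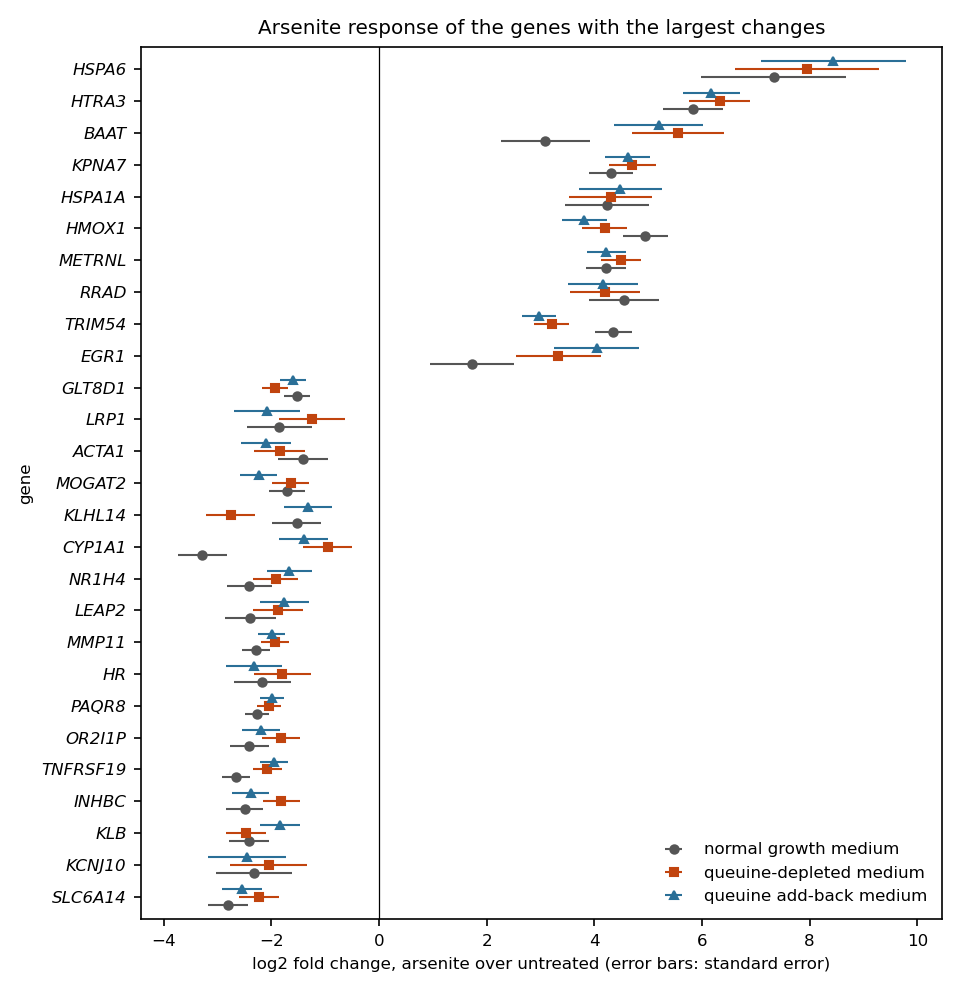
Log2 fold change of arsenite-treated over untreated cells (horizontal axis) for each gene named for its large rise or fall in at least 1 medium (vertical axis), from the authors' deposited tables. Points stand for the 3 media and error bars for the standard error, and HSPA6 leads with 7.33, 7.95 and 8.44 in normal, depleted and add-back medium.

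Of the heat shock genes, 16 of 24 rose (19 adjusted over the list alone; cameraPR adjusted p = 8.13e-19). They included the small chaperone HSPB1 (3.23 ± 0.41), the Hsp110 protein HSPH1 (3.02 ± 0.49), the collagen chaperone SERPINH1 (2.41 ± 0.35) and the Hsp90 co-chaperone FKBP4 (1.70 ± 0.30), at DESeq2 adjusted p of at most 2.14e-06 in the authors' deposited table. HSPA1A shares most of its sequence with HSPA1B, so the split of reads between the pair is uncertain. NRF2 targets rose in 12 of 30 members (13 adjusted over the list alone; cameraPR adjusted p = 3.33e-11). The cystine importer SLC7A11 (2.86 ± 0.45), the autophagy receptor SQSTM1 (2.01 ± 0.34) and the glutathione synthesis subunit GCLM (2.10 ± 0.43) were among them, at DESeq2 adjusted p of at most 7.15e-05 in the authors' deposited table. Metallothioneins and zinc exporters had 2 of 8 members rise (2 adjusted over the list alone; cameraPR adjusted p = 0.0152). These were MT1M (1.88 ± 0.61) and MT1X (2.73 ± 0.92), at DESeq2 adjusted p of at most 0.0366 in the authors' deposited table. MT2A was at 1.55 ± 0.69 (DESeq2 adjusted p = 0.149) in the authors' deposited table, and the split of reads among these near-identical genes is uncertain.

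Immediate early genes, transcription factors and phosphatases switched on within minutes of a stimulus, rose in 5 of 19 members (5 adjusted over the list alone; cameraPR adjusted p = 1.5e-06). They included KLF4 (5.36 ± 0.71), DUSP5 (3.22 ± 0.50), ARC (4.52 ± 1.04) and FOSL1 (1.84 ± 0.45), at DESeq2 adjusted p of at most 0.00157 in the authors' deposited table. Of the ATF4 targets of the integrated stress response, 3 of 26 rose and 1 fell (5 and 1 adjusted over the list alone). Their cameraPR adjusted p was 0.00701, and 0.0543 at a correlation of 0.05. The cysteine-forming enzyme CTH rose by 2.75 ± 0.35, the stress sensor SESN2 by 1.23 ± 0.43 and the lipoprotein receptor VLDLR by 2.24 ± 0.41, at DESeq2 adjusted p of at most 0.0462 in the authors' deposited table. STC2 fell by 0.94 ± 0.27 (DESeq2 adjusted p = 0.00892) in the authors' deposited table. DDIT3, the gene of the stress factor CHOP, was at 0.48 ± 0.94 (DESeq2 adjusted p = 0.841) in the authors' deposited table.

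Arsenic handling genes rose in 3 of 12 members (3 higher and 1 lower adjusted over the list alone; cameraPR adjusted p = 0.00516). The aquaglyceroporin AQP3 rose by 3.88 ± 0.36, the glutathione-conjugate exporter ABCC1 by 1.36 ± 0.29 and PNP by 0.80 ± 0.27, at DESeq2 adjusted p of at most 0.0354 in the authors' deposited table. In iron handling, 4 of 13 genes rose and 2 fell (4 and 2 adjusted over the list alone; cameraPR adjusted p = 0.00546). The iron exporter SLC40A1 rose by 1.89 ± 0.33 and BMP6, an inducer of hepcidin, by 4.58 ± 0.74, at DESeq2 adjusted p of at most 1.79e-06 in the authors' deposited table. The iron importer SLC11A2 fell by 1.11 ± 0.25 (DESeq2 adjusted p = 0.000404) in the authors' deposited table. Proteasome subunits rose in 3 of 27 (3 adjusted over the list alone; cameraPR adjusted p = 0.000246), with PSMD12 at 1.21 ± 0.30 (DESeq2 adjusted p = 0.00172) in the authors' deposited table. Aminoacyl-tRNA synthetases rose in 5 of 20 (6 adjusted over the list alone), led by CARS1 at 1.70 ± 0.30 (DESeq2 adjusted p = 2.65e-06) in the authors' deposited table. Their cameraPR adjusted p was 0.0175, and 0.0775 at a correlation of 0.05. Of the selenoproteins, 1 of 21 rose (1 adjusted over the list alone; cameraPR adjusted p = 0.767), TXNRD1, which reduces thioredoxin, by 1.85 ± 0.43 (DESeq2 adjusted p = 0.000663) in the authors' deposited table.

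Replication-dependent histone genes, whose transcripts mostly lack poly(A) tails, rose in 5 of 10 (6 adjusted over the list alone; cameraPR adjusted p = 0.000149). H2BC21 was at 2.15 ± 0.50 (DESeq2 adjusted p = 0.000618) in the authors' deposited table, and reads of these similar genes may be split unevenly. Also without poly(A) tails, 5 genes and copies of the 7SL RNA had a median of 2.02 and 5 of the 7SK RNA of 1.98, with 0 called by DESeq2 and 0 at an unadjusted p under 0.05.

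Cholesterol and fatty acid synthesis genes fell in 10 of 26 members (15 adjusted over the list alone; cameraPR adjusted p = 7.91e-11). Mevalonate kinase MVK fell by 1.57 ± 0.28 and squalene epoxidase SQLE by 1.84 ± 0.36, at DESeq2 adjusted p of at most 2.45e-05 in the authors' deposited table. Cell cycle genes fell in 6 of 25 (8 adjusted over the list alone; cameraPR adjusted p = 0.0001). The replication genes PCNA (-0.74 ± 0.19), MCM3 (-1.08 ± 0.30), MCM7 (-0.98 ± 0.28) and MCM6 (-0.84 ± 0.26) fell, at DESeq2 adjusted p of at most 0.0198 in the authors' deposited table. Of 19 genes of the reticulum's unfolded protein response, 2 fell (4 adjusted over the list alone; cameraPR adjusted p = 0.00012). These were the chaperone HSPA5 (-1.25 ± 0.20) and SEL1L (-0.88 ± 0.29), at DESeq2 adjusted p of at most 0.03 in the authors' deposited table. Aryl hydrocarbon receptor targets fell in 2 of 5 (2 adjusted over the list alone; cameraPR adjusted p = 0.0152), CYP1A1 and CYP1A2, the latter by 4.65 ± 1.40 (DESeq2 adjusted p = 0.0152) in the authors' deposited table. NF-kappaB and inflammatory genes had 1 rise and 3 falls among 16 (1 and 3 adjusted over the list alone). They stood below other genes by cameraPR, at an adjusted p of 0.0175, and 0.0727 at a correlation of 0.05. The cytokine IL11 rose by 2.91 ± 0.72 and the chemokine CCL20 fell by 1.68 ± 0.41, at DESeq2 adjusted p of at most 0.0017 in the authors' deposited table.

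Hepatocyte enzymes and regulators had 1 rise and 2 falls among 20 (2 and 4 adjusted over the list alone; cameraPR adjusted p = 0.181). The urea cycle enzyme CPS1 fell by 1.19 ± 0.31 and the bile acid repressor NR0B2 rose by 1.16 ± 0.37, at DESeq2 adjusted p of at most 0.0256 in the authors' deposited table. Hypoxia and glycolysis genes had 2 rises and 2 falls among 17 (3 and 2 adjusted over the list alone; cameraPR adjusted p = 0.924). The glycolysis regulators PFKFB3 (1.65 ± 0.36) and PFKFB4 (-1.33 ± 0.38) moved apart, at DESeq2 adjusted p of at most 0.00944 in the authors' deposited table. Of the p53 targets, 1 of 18 rose, PLK3 (1 adjusted over the list alone; cameraPR adjusted p = 0.751). Markers of other cell types had 2 falls among 15 (2 adjusted over the list alone; cameraPR adjusted p = 0.767). These were the growth factor receptor PDGFRB (-0.84 ± 0.26) and the monocyte receptor CD14 (-1.26 ± 0.39), at DESeq2 adjusted p of at most 0.0205 in the authors' deposited table.

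By DESeq2, 0 mitochondrially encoded, 0 nuclear oxidative phosphorylation and 0 hepatocyte secreted protein genes were called over all genes or adjusted over the list alone (0, 0 and 2 at an unadjusted p under 0.05). Their cameraPR adjusted p were 0.76, 0.844 and 0.65. The same held for interferon response genes, YAP and TGF-beta responsive genes and cytosolic ribosomal proteins, with 0 called and 2, 2 and 2 at an unadjusted p under 0.05. Their cameraPR adjusted p were 0.702, 0.784 and 0.0175, the last 0.105 at a correlation of 0.05. Queuosine and tRNA modification genes had 0 calls by DESeq2, 5 at an unadjusted p under 0.05 and a cameraPR adjusted p of 0.057. QTRT1 was at -0.29 ± 0.26, QTRT2 at 0.02 ± 0.22 and the tRNA methyltransferase ALKBH8 at 0.03 ± 0.38, with DESeq2 adjusted p of 0.6, 0.977 and 0.977 in the authors' deposited table. Median, mean and test of a list differed in sign in 48 of 324 list tests over the 12 comparisons, of which 0 had a cameraPR adjusted p under 0.05 (smallest 0.0604). DESeq2 takes the Wald statistic as normal. With a t distribution of 12 degrees of freedom 531 genes passed. With 4 degrees of freedom 0 passed, and 1792 of 35013 had an unadjusted p under 0.05, about the share expected without any effect.

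**Figure D2:**
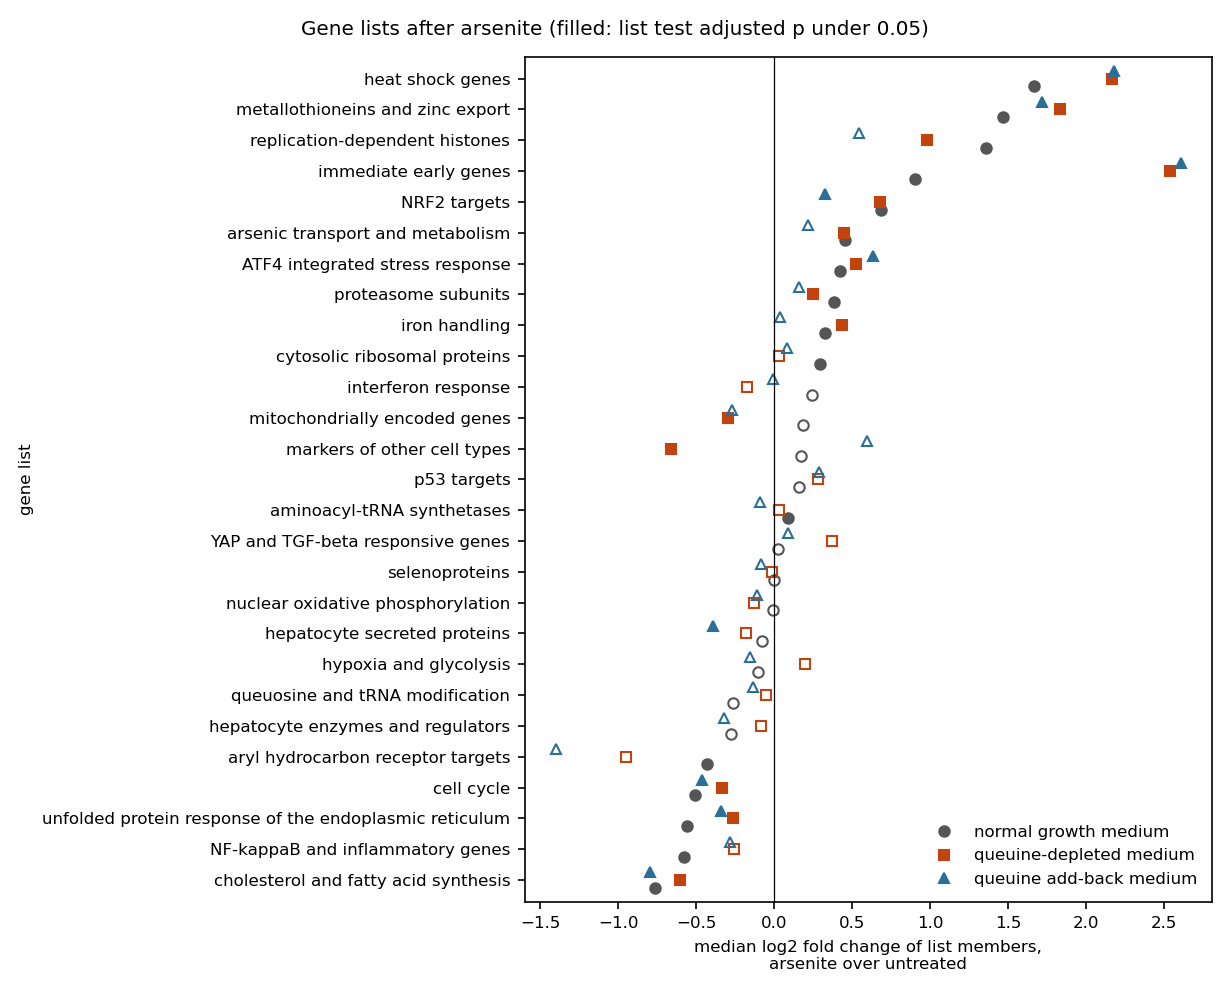
Median log2 fold change of arsenite-treated over untreated cells (horizontal axis) over the members of each gene list (vertical axis) in the 3 media. Filled points have a cameraPR adjusted p under 0.05, and heat shock genes lie at 1.66, 2.16 and 2.18 in normal, depleted and add-back medium.

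In queuine-depleted medium, arsenite raised most heat shock and immediate early genes and part of the NRF2 targets, and lowered part of the cholesterol synthesis and cell cycle genes. HSPA6 rose by 7.95 ± 1.35 (DESeq2 adjusted p = 7.96e-07), HMOX1 by 4.19 ± 0.42 (DESeq2 adjusted p = 2.89e-20) and HSPA1A by 4.30 ± 0.78 (DESeq2 adjusted p = 6.13e-06) in the authors' deposited table. The bile acid conjugating enzyme BAAT rose by 5.55 ± 0.85, HTRA3 by 6.33 ± 0.57, KPNA7 by 4.71 ± 0.43, METRNL by 4.49 ± 0.37 and RRAD by 4.20 ± 0.65, at DESeq2 adjusted p of at most 4.72e-08 in the authors' deposited table. Large falls were those of KLHL14 (-2.76 ± 0.46), KLB (-2.47 ± 0.37), SLC6A14 (-2.24 ± 0.37) and TNFRSF19 (-2.07 ± 0.27) in the authors' deposited table. The membrane progestin receptor PAQR8 (-2.04 ± 0.22), GLT8D1 (-1.93 ± 0.24), the metalloproteinase MMP11 (-1.93 ± 0.26) and NR1H4 (-1.92 ± 0.42) followed in the authors' deposited table, and these 8 had DESeq2 adjusted p of at most 0.000319. In all, 975 genes rose and 465 fell, with 3656 at an unadjusted p under 0.05 in the authors' deposited table.

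Immediate early genes rose in 16 of 19 members here (17 adjusted over the list alone; cameraPR adjusted p = 6.91e-18). They included DUSP5 (3.48 ± 0.51), IER3 (1.95 ± 0.33), FOSL1 (2.54 ± 0.45) and KLF4 (3.57 ± 0.64), at DESeq2 adjusted p of at most 5.23e-06 in the authors' deposited table. Heat shock genes rose in 17 of 24 (22 adjusted over the list alone; cameraPR adjusted p = 2.59e-25) and NRF2 targets in 10 of 30 (15 adjusted over the list alone; cameraPR adjusted p = 6.09e-11). HSPH1 rose by 3.56 ± 0.49, SLC7A11 by 2.86 ± 0.45 and the zinc exporter SLC30A1 by 2.40 ± 0.82, at DESeq2 adjusted p of at most 0.0431 in the authors' deposited table. Metallothioneins and zinc exporters had 2 of 8 rise (5 adjusted over the list alone; cameraPR adjusted p = 0.00258). ATF4 targets rose in 4 of 25 (8 adjusted over the list alone; cameraPR adjusted p = 0.000254), with the phosphatase subunit PPP1R15A at 3.01 ± 0.74 (DESeq2 adjusted p = 0.00191) in the authors' deposited table. DDIT3 was at 2.48 ± 0.93 (DESeq2 adjusted p = 0.0763) in the authors' deposited table.

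Cholesterol and fatty acid synthesis genes fell in 7 of 26 in depleted medium (11 adjusted over the list alone; cameraPR adjusted p = 5.59e-06), with the desaturase SCD at -1.15 ± 0.23 (DESeq2 adjusted p = 4.05e-05) in the authors' deposited table. Cell cycle genes fell in 4 of 25 and rose in 1 (5 and 1 adjusted over the list alone; cameraPR adjusted p = 0.00375). TOP2A fell by 0.98 ± 0.28 and MCM6 by 0.98 ± 0.26, while the cyclin CCNE1 rose by 0.81 ± 0.24, at DESeq2 adjusted p of at most 0.0143 in the authors' deposited table. Among queuosine and tRNA modification genes, the thiolation enzyme CTU1 rose by 0.91 ± 0.27 (DESeq2 adjusted p = 0.0165) in the authors' deposited table. GTDC1, which mannosylates queuosine, fell by 1.27 ± 0.32 (DESeq2 adjusted p = 0.00308) in the authors' deposited table, and the list had a cameraPR adjusted p of 0.371. QTRT1 was at -0.29 ± 0.26, QTRT2 at 0.18 ± 0.23, ALKBH8 at 0.14 ± 0.38 and MT2A at 1.80 ± 0.69 in the authors' deposited table, with DESeq2 adjusted p of 0.605, 0.741, 0.897 and 0.0839. CYP1A1 was at -0.95 ± 0.46 (DESeq2 adjusted p = 0.206) in the authors' deposited table.

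Replication-dependent histones rose in 2 of 10 in this medium (4 adjusted over the list alone; cameraPR adjusted p = 0.00604), with a 7SL median of 1.92. Arsenic handling genes rose in 2 of 12 (2 adjusted over the list alone; cameraPR adjusted p = 0.00805). Several lists called by cameraPR lost the call at a correlation of 0.05. These were iron handling (adjusted p = 0.0299, then 0.0903), proteasome subunits (0.0299, then 0.129), the reticulum's unfolded protein response (0.0101, then 0.0603), mitochondrially encoded genes (0.0433, then 0.117) and markers of other cell types (0.0323, then 0.102). The last 3 stood below other genes and the others above. Among the last, the collagen gene COL1A1 fell by 3.75 (DESeq2 adjusted p = 0.00501) in the authors' deposited table. A lymphoid list of 24 detected genes, written after the tables were seen, had a median of -1.02. With a t distribution of 12 degrees of freedom 299 genes passed. With 4 degrees of freedom 0 passed, and 1602 of 35013 had an unadjusted p under 0.05, no more than expected without any effect.

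In queuine add-back medium, most heat shock and immediate early genes and part of the NRF2 targets rose after arsenite, and part of the cholesterol synthesis genes fell. HSPA6 rose by 8.44 ± 1.34 (DESeq2 adjusted p = 1.12e-07), HSPA1A by 4.48 ± 0.78 (DESeq2 adjusted p = 1.6e-06) and HMOX1 by 3.81 ± 0.42 (DESeq2 adjusted p = 1.5e-16) in the authors' deposited table. HTRA3 rose by 6.17 ± 0.53, BAAT by 5.19 ± 0.83, KPNA7 by 4.62 ± 0.42, METRNL by 4.22 ± 0.36, RRAD by 4.16 ± 0.65 and the immediate early factor EGR1 by 4.04 ± 0.79, at DESeq2 adjusted p of at most 3.68e-05 in the authors' deposited table. Large falls were those of SLC6A14 (-2.54 ± 0.37), the potassium channel KCNJ10 (-2.46 ± 0.72), INHBC (-2.38 ± 0.34) and the corepressor HR (-2.32 ± 0.53) in the authors' deposited table. The acyltransferase MOGAT2 (-2.24 ± 0.34), OR2I1P (-2.19 ± 0.35), the actin ACTA1 (-2.10 ± 0.47) and the lipoprotein receptor LRP1 (-2.08 ± 0.61) followed in the authors' deposited table, and these 8 had DESeq2 adjusted p of at most 0.0141. In all, 909 genes rose and 560 fell, with 3859 at an unadjusted p under 0.05 in the authors' deposited table.

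Heat shock genes rose in 17 of 24 members in add-back medium (22 adjusted over the list alone; cameraPR adjusted p = 1.37e-26). Immediate early genes rose in 16 of 19 (17 adjusted over the list alone; cameraPR adjusted p = 6.91e-19) and NRF2 targets in 9 of 30 (9 higher and 1 lower adjusted over the list alone; cameraPR adjusted p = 0.000164). DUSP5 was at 3.65 ± 0.50, ARC at 4.31 ± 0.83, SLC7A11 at 3.01 ± 0.45 and TXNRD1 at 1.65 ± 0.43, at DESeq2 adjusted p of at most 0.00434 in the authors' deposited table. Of the ATF4 targets 8 of 26 rose and 1 fell (10 and 2 adjusted over the list alone; cameraPR adjusted p = 0.00093), and DDIT3 rose by 2.91 ± 0.93 (DESeq2 adjusted p = 0.0279) in the authors' deposited table. Metallothioneins and zinc exporters rose in 2 of 8 (5 adjusted over the list alone; cameraPR adjusted p = 0.00745). CTU1 rose by 0.78 ± 0.27 (DESeq2 adjusted p = 0.0466) in the authors' deposited table. MT2A was at 1.65 ± 0.69, QTRT1 at -0.46 ± 0.26, QTRT2 at 0.34 ± 0.22 and ALKBH8 at 0.34 ± 0.38 in the authors' deposited table, with DESeq2 adjusted p of 0.124, 0.31, 0.406 and 0.651.

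Cholesterol and fatty acid synthesis genes fell in 11 of 26 in add-back medium (13 adjusted over the list alone; cameraPR adjusted p = 5.48e-10) and cell cycle genes in 4 of 25 (4 adjusted over the list alone; cameraPR adjusted p = 0.000249). MCM7 fell by 1.02 ± 0.28 (DESeq2 adjusted p = 0.00704) in the authors' deposited table. Of 19 genes of the reticulum's unfolded protein response 2 fell (3 adjusted over the list alone; cameraPR adjusted p = 0.00157). Hepatocyte secreted proteins fell in 1 of 22 (1 adjusted over the list alone; cameraPR adjusted p = 0.00481), the acute-phase protein ORM1 by 0.90 ± 0.22 (DESeq2 adjusted p = 0.00204) in the authors' deposited table. CYP1A1 fell by 1.40 ± 0.46 (DESeq2 adjusted p = 0.0324) and ALDH3A1, another aryl hydrocarbon receptor target, by 1.76 ± 0.48 (DESeq2 adjusted p = 0.00675) in the authors' deposited table. The lymphoid list had a median of 1.50, with 1 of 24 genes called. With a t distribution of 12 degrees of freedom 315 genes passed. With 4 degrees of freedom 0 passed, and 1630 of 35013 had an unadjusted p under 0.05, no more than expected without any effect.

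Many genes responded to arsenite in all 3 media. Of the 1529 genes that rose in any medium 464 rose in all 3, and of the 1081 that fell in any 212 fell in all 3. By DESeq2, 0 genes were called in opposite directions. Normal and depleted medium shared 595 risen and 306 fallen genes, against 53.4 and 20.1 for independent lists. Normal and add-back medium shared 578 and 347, against 48.2 and 23.4. Depleted and add-back medium shared 602 and 256, against 50.5 and 14.9. These comparisons share no libraries. Over genes chosen for their call in the medium left out of a pair, Pearson's r of the fold changes across genes was between 0.941 and 0.965, where genes are not independent replicates. With an adjusted p under 0.01, 253 genes rose and 80 fell in all 3 media.

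The next question was whether the response depends on queuine. The arsenite response of immediate early genes as a list was higher in both processed-serum media than in normal medium. Their median difference was 1.10 in depleted (cameraPR adjusted p = 4.64e-05) and 0.99 in add-back medium (cameraPR adjusted p = 1.91e-06). Add-back minus depleted medium gave 0.05 (cameraPR adjusted p = 0.784). Both differences from normal medium subtract the same normal-medium libraries, here and for the lists that follow. They are therefore not independent findings. The aryl hydrocarbon receptor targets, which include CYP1A1, differed likewise by 1.42 in depleted (cameraPR adjusted p = 0.00255) and 1.27 in add-back medium (cameraPR adjusted p = 0.0396, and 0.0661 at a correlation of 0.05). For mitochondrially encoded genes the median difference was -0.47 in depleted (cameraPR adjusted p = 0.000275, and 0.286 with GC and length trends removed) and -0.43 in add-back medium (cameraPR adjusted p = 0.00165). By the z test on folds of the authors' deposited tables, 0 single genes differed between depleted and normal and 0 between add-back and normal medium, with 283 and 210 at an unadjusted p under 0.05. Of 14585 genes tested, that is fewer than the share of 0.05 expected without any effect.

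NRF2 targets had a median difference of -0.32 for add-back minus normal medium (cameraPR adjusted p = 0.000228). For add-back minus depleted medium it was -0.35 (cameraPR adjusted p = 0.00555, and 0.18 at a correlation of 0.05). For HMOX1 the differences between folds of the authors' deposited tables were -0.76 ± 0.59 for depleted and -1.14 ± 0.59 for add-back minus normal medium, with z test adjusted p of 1 and 1. DDIT3 had differences of 1.99 ± 1.32 and 2.42 ± 1.32 between the same folds, with z test adjusted p of 1 and 1. Add-back minus depleted medium, which by design differ only in queuine, called 1 gene, with 258 at an unadjusted p under 0.05. This was FLNC, an actin cross-linker on chromosome 7 at 128830377 to 128859274, with a difference of 4.31 ± 0.88 (z test adjusted p = 0.0165). It was named after its values were seen, since its mean of 39.5 normalized counts lies below the minimum set for the largest changes. Its rebuilt means, from the authors' deposited tables, were 6.13, 30.4 and 3.46 in untreated cells of normal, depleted and add-back medium, and 85.9, 34.2 and 77.0 in treated cells. Over genes with a mean of at least 100, or by the route through the medium comparisons, 0 genes were called by the z test. At the median standard error of 0.42, 39.1% to 45.1% of well-expressed genes had a 95% interval within 2-fold in these 3 tests.

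**Figure D3:**
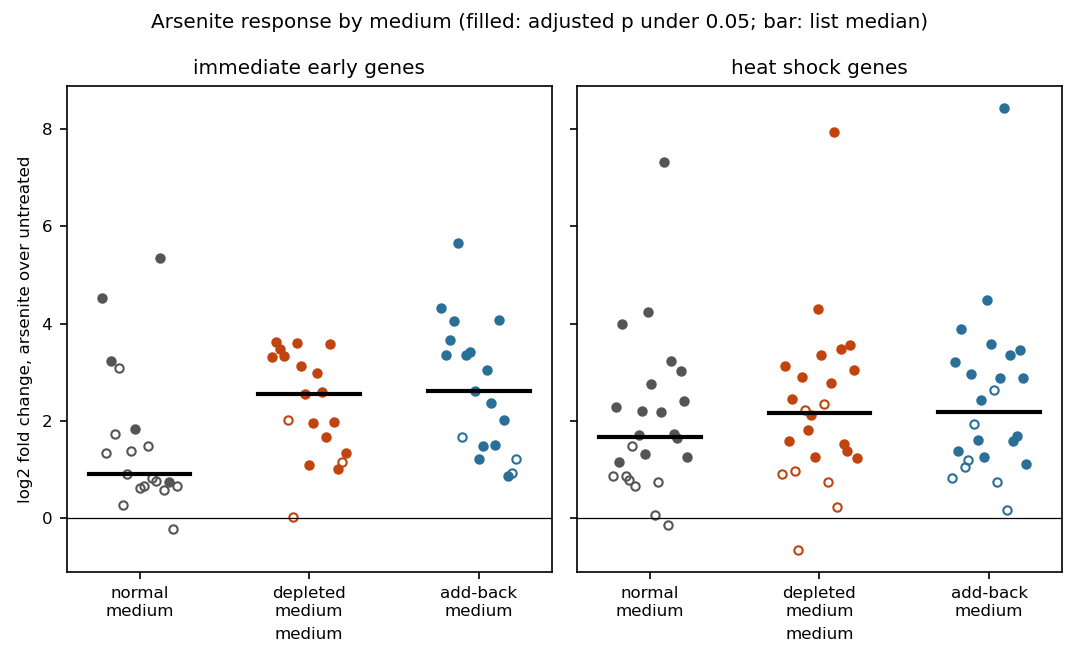
Log2 fold change of arsenite-treated over untreated cells (vertical axis) for each immediate early gene and each heat shock gene in the 3 media (horizontal axis), from the authors' deposited tables. Filled points had a DESeq2 adjusted p under 0.05 and bars are list medians, 0.90, 2.54 and 2.61 for immediate early genes in normal, depleted and add-back medium.

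The medium comparisons ask what the serum treatment and queuine do to cells without and with arsenite. In untreated cells, depleted medium raised 18 genes and lowered 16, with 1882 at an unadjusted p under 0.05 in the authors' deposited table. The trypsin inhibitor SPINK1 rose by 2.47 ± 0.50 (DESeq2 adjusted p = 0.00134), the oligosaccharyltransferase subunit TUSC3 by 2.39 ± 0.40 (DESeq2 adjusted p = 2.94e-05) and the liver factor CREB3L3 by 2.02 ± 0.43 (DESeq2 adjusted p = 0.00317) in the authors' deposited table. The growth factor receptor PDGFRB, on chromosome 5 at 150113837 to 150155872, fell by 1.93 ± 0.26 (DESeq2 adjusted p = 4.51e-09) in the authors' deposited table. Plasminogen PLG (2.26 ± 0.54), VLDLR (2.14 ± 0.41), the RNA-binding protein LARP6 (1.88 ± 0.33), the kinase PAK1 (1.57 ± 0.33) and the calcium sensor SCGN (1.54 ± 0.29) also rose, at DESeq2 adjusted p of at most 0.0201 in the authors' deposited table. The semaphorin receptor PLXNA2 (-1.76 ± 0.40), MCC (-1.69 ± 0.36), DOCK4 (-1.59 ± 0.30) and the signalling inhibitor SPRY4 (-1.44 ± 0.37) fell, at DESeq2 adjusted p of at most 0.0494 in the authors' deposited table. HMOX1 was at 1.23 ± 0.42 (DESeq2 adjusted p = 0.22), QTRT1 at 0.23 ± 0.26, QTRT2 at -0.34 ± 0.22 and ALKBH8 at -0.50 ± 0.38 in the authors' deposited table, with DESeq2 adjusted p of at least 0.22. HSPA1A was at 1.06 ± 0.78, MT2A at -0.53 ± 0.69 and DDIT3 at 0.51 ± 0.94 in the authors' deposited table, with DESeq2 adjusted p of 0.728, 0.895 and 0.939. Of the called genes 52.9% were higher, and 69.0% of 42 with folds centred on their median.

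Cytosolic ribosomal protein genes stood higher in untreated depleted-medium cells (median 0.51; 7 of 30 members higher adjusted over the list alone; cameraPR adjusted p = 1.56e-11). So did aryl hydrocarbon receptor targets (3 of 5 higher adjusted over the list alone; cameraPR adjusted p = 0.00325), hepatocyte secreted proteins (cameraPR adjusted p = 0.00401) and replication-dependent histones (cameraPR adjusted p = 0.0064), and cell cycle genes stood lower (cameraPR adjusted p = 0.00325). Proteasome subunits (cameraPR adjusted p = 0.00434), interferon response genes (0.00695) and nuclear oxidative phosphorylation genes (0.00591) were higher too. At a correlation of 0.05 these 3 had adjusted p of 0.0504, 0.0504 and 0.0716. Folds of this comparison fell with transcript length across genes, which are not independent replicates (Spearman's rho = -0.359). With GC and length trends removed, chosen after seeing the data, cameraPR adjusted p was 2.34e-07 for ribosomal proteins, 0.0434 for proteasome subunits and 0.0298 for interferon genes. It was 0.294 for oxidative phosphorylation, 0.102 for secreted proteins and 0.114 for histones, whose calls were lost. Of the lymphoid list, 24 of 24 detected genes had a higher value than in normal medium, by a median of 2.57, with 0 called by DESeq2 and 19 at an unadjusted p under 0.05. LCK had rebuilt means of 80.2 and 315 and CD3E of 30.6 and 178 normalized counts in untreated normal-medium and depleted-medium cells, from the authors' deposited tables. The 7SL and 7SK genes and copies, named after their values were seen, had medians of 1.43 and 2.17, with 0 called by DESeq2 and 0 at an unadjusted p under 0.05.

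In arsenite-treated cells, depleted against normal medium gave a rise of 3.41 ± 0.46 (DESeq2 adjusted p = 1.48e-09) for CYP1A1 in the authors' deposited table. Its rebuilt means were 3044 and 285 normalized counts, from the authors' deposited tables. SPINK1 (2.51 ± 0.49), SECTM1 (1.52 ± 0.35), SCGN (1.48 ± 0.29), RAB3IL1 (1.41 ± 0.31), CDH16 (1.25 ± 0.31) and the chemerin gene RARRES2 (1.07 ± 0.27) also rose, at DESeq2 adjusted p of at most 0.0487 in the authors' deposited table. The cytochrome P450 CYP2S1 fell by 1.92 ± 0.46, the growth factor IGF2 by 1.78 ± 0.44, MCC by 1.68 ± 0.38 and the copper-carrying ceruloplasmin CP by 1.58 ± 0.32, at DESeq2 adjusted p of at most 0.0468 in the authors' deposited table. The Wnt inhibitor DKK1 fell by 1.19 ± 0.30, PDGFRB by 1.18 ± 0.27 and STRN by 1.17 ± 0.27, at DESeq2 adjusted p of at most 0.0468 in the authors' deposited table. In all, 10 genes rose and 11 fell, with 1260 at an unadjusted p under 0.05 in the authors' deposited table. Of the called genes 47.6% were higher, and 33.3% of 21 with centred folds.

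As lists, immediate early genes stood higher in treated depleted-medium cells (median 0.96, cameraPR adjusted p = 8.13e-06), as did aryl hydrocarbon receptor targets (cameraPR adjusted p = 1.23e-06) and heat shock genes (0.00285). NF-kappaB and inflammatory genes stood higher as well (4 higher and 1 lower of 13 adjusted over the list alone; cameraPR adjusted p = 0.000376). Ribosomal protein genes (cameraPR adjusted p = 0.00285, and 0.0591 at a correlation of 0.05) and ATF4 targets (0.0351, and 0.18 at that correlation) lost their call. Folds fell with transcript length here too, across genes (Spearman's rho = -0.317), and with the trends removed cameraPR adjusted p was 0.0658 for ribosomal proteins and 0.0673 for ATF4 targets. Mitochondrially encoded genes stood lower (median -0.50; 3 of 13 lower adjusted over the list alone; cameraPR adjusted p = 8.13e-06), with MT-CO1 at -0.78 ± 0.38 (DESeq2 adjusted p = 0.636) in the authors' deposited table. The lymphoid list had a median of 0.58, with 0 called by DESeq2 and 0 at an unadjusted p under 0.05.

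With queuine added back, PLG and SPINK1 were again among the genes that were higher in untreated cells than in normal medium. PLG rose by 2.55 ± 0.54 (DESeq2 adjusted p = 0.00431), SPINK1 by 2.53 ± 0.50 (DESeq2 adjusted p = 0.000937) and ALDH3A1 by 2.14 ± 0.48 (DESeq2 adjusted p = 0.00963) in the authors' deposited table. RAB3IL1 (1.95 ± 0.32), CREB3L3 (1.92 ± 0.43), TUSC3 (1.81 ± 0.41), the cell cycle inhibitor CDKN2A (1.80 ± 0.41) and LARP6 (1.80 ± 0.33) rose, at DESeq2 adjusted p of at most 0.0116 in the authors' deposited table. MCC (-1.69 ± 0.36), DKK1 (-1.50 ± 0.30), DOCK4 (-1.46 ± 0.30), SLC37A2 (-1.42 ± 0.28) and PDGFRB (-1.37 ± 0.26) fell, at DESeq2 adjusted p of at most 0.0045 in the authors' deposited table. In all, 17 genes rose and 8 fell, with 1190 at an unadjusted p under 0.05 in the authors' deposited table. Ribosomal protein genes stood higher (median 0.48, cameraPR adjusted p = 2.63e-14). So did NRF2 targets (median 0.34; 3 of 30 higher adjusted over the list alone; cameraPR adjusted p = 5.28e-07) and hepatocyte secreted proteins (4 of 22 higher adjusted over the list alone; cameraPR adjusted p = 5.28e-07). Proteasome subunits (cameraPR adjusted p = 5.19e-05), aryl hydrocarbon receptor targets (8.58e-05) and nuclear oxidative phosphorylation genes (0.000288) were higher, and cell cycle genes lower (0.00427, and 0.0552 at a correlation of 0.05). Hepatocyte enzymes and regulators had a cameraPR adjusted p of 0.353. Folds fell with transcript length across genes (Spearman's rho = -0.446), and with GC and length trends removed the largest cameraPR adjusted p of these 7 called lists was 0.0225, for oxidative phosphorylation. HMOX1 was at 1.52 ± 0.42 (DESeq2 adjusted p = 0.0996) in the authors' deposited table.

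In arsenite-treated cells, add-back against normal medium raised CYP1A1 by 3.25 ± 0.46 (DESeq2 adjusted p = 1.96e-08) and SPINK1 by 3.13 ± 0.49 (DESeq2 adjusted p = 9.52e-07) in the authors' deposited table. TUSC3 (1.57 ± 0.38), RAB3IL1 (1.28 ± 0.31) and RARRES2 (1.15 ± 0.27) rose, and DKK1 (-1.42 ± 0.30) and PDGFRB (-1.18 ± 0.27) fell, at DESeq2 adjusted p of at most 0.0478 in the authors' deposited table. In all, 6 genes rose and 4 fell, with 1183 at an unadjusted p under 0.05 in the authors' deposited table. Immediate early genes stood higher (median 1.01, cameraPR adjusted p = 8.63e-07), with aryl hydrocarbon receptor targets (1.44e-06), ribosomal protein genes (3.93e-05), NF-kappaB and inflammatory genes (0.0017) and heat shock genes (0.00179). Mitochondrially encoded genes stood lower (median -0.66, cameraPR adjusted p = 2.54e-07). Calls by cameraPR of ATF4 targets (adjusted p = 0.0199, then 0.121), cell cycle genes (0.0374, then 0.163) and aminoacyl-tRNA synthetases, which stood lower like the cell cycle genes (0.0191, then 0.108) were lost at a correlation of 0.05. With GC and length trends removed, 7 of these 9 list calls were kept. In the lymphoid list 24 of 24 genes had a higher value, by a median of 0.88, with 0 called by DESeq2 and 0 at an unadjusted p under 0.05. The 7SL and 7SK genes and copies had medians of -2.41 and -2.50, with 0 called by DESeq2 and 2 and 1 at an unadjusted p under 0.05. With a t distribution of 12 degrees of freedom, each of the 4 medium comparisons called 0 genes. Of 35013 genes, 764 to 1323 had an unadjusted p under 0.05, fewer than the share of 0.05 expected without any effect.

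Depleted and add-back medium shared part of their calls against normal medium. They had 10 risen and 5 fallen genes in common in untreated cells, against 0.0176 and 0.00736 for independent lists, and in treated cells 5 and 2, against 0.00445 and 0.00327. Both comparisons use the same normal-medium libraries, so independence does not hold for these overlaps. Pearson's r of the folds across genes was 0.745 in untreated and 0.826 in treated cells, against 0.499 and 0.50 in simulations with shared controls and without any effect. The covariance was 0.101 and 0.107 against 0.0528 and 0.0532, and genes are not independent replicates. Folds of both media fell with transcript length, and trends or library variation common to both media would also raise r. The simulations without any effect do not include these, so the higher r does not by itself show an effect of the media.

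**Figure D4:**
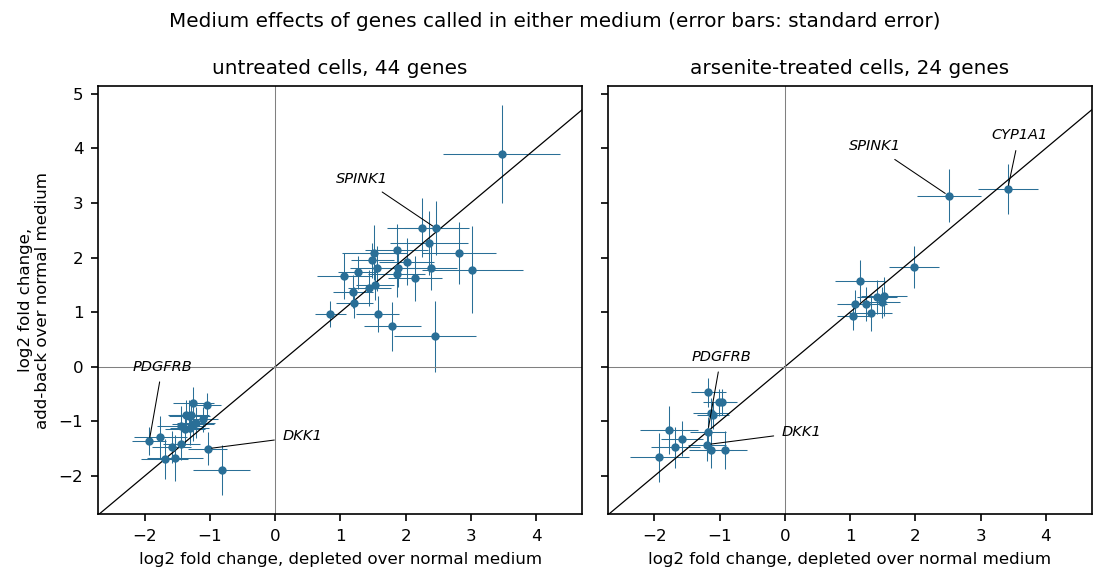
Log2 fold change of add-back over normal medium (vertical axis) against that of depleted over normal medium (horizontal axis), from the authors' deposited tables, for the 44 genes called in either medium in untreated cells and the 24 in arsenite-treated cells. Error bars are standard errors and the diagonal marks equal change, near which SPINK1 lies in untreated cells at 2.47 and 2.53.

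Add-back and depleted medium differ by design only in queuine. Folds between them also followed transcript GC content across genes, which are not independent replicates (Spearman's rho = 0.641 untreated and -0.353 treated). A difference between the libraries is therefore not excluded as a source of what follows. With GC and length trends removed, the 2 list calls in untreated and the 1 in treated cells were kept. Untreated cells had NRF2 targets higher in add-back medium (median 0.21, cameraPR adjusted p = 0.00721, and 0.145 at a correlation of 0.05) and markers of other cell types lower (median -0.27, cameraPR adjusted p = 0.00721, and 0.101 at that correlation). The lymphoid list moved with the latter, at a median of -2.31. In treated cells replication-dependent histones stood lower in add-back medium (median -0.90, cameraPR adjusted p = 2.8e-09). Over a wider set of 35 such genes the median was -1.24, with 0 called by the z test and 0 at an unadjusted p under 0.05. The list call was kept at a correlation of 0.05, though the true correlation of these similar genes could not be estimated. The 7SL (median -4.00) and 7SK RNAs (median -4.86) moved with the histones, with 0 genes called by the z test and 3 and 4 at an unadjusted p under 0.05. Over all genes the z test on folds of the authors' deposited tables called 0 in untreated and 0 in treated cells, with 95 and 9 at an unadjusted p under 0.05. Its standard error is too large because of the shared controls. With the rebuilt standard error 0 and 0 were called as well, and with that z scaled to its spread, chosen after seeing the data, 13 in untreated cells, all lower, and 27 in treated cells, 10 higher and 17 lower.

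Of the 44 and 24 genes called against normal medium, 0 and 0 differed between add-back and depleted medium by the z test with the rebuilt standard error, adjusted over these alone, with 4 and 1 at an unadjusted p under 0.05. The smallest adjusted p were 0.0847 for SETD7 (-1.89, 95% interval -3.09 to -0.70) and 0.198 for STRN (0.71, 0.18 to 1.24), named after their values were seen. HMOX1 had a difference of 0.29 ± 0.59 untreated and -0.09 ± 0.59 treated, QTRT1 of 0.09 ± 0.37 and -0.07 ± 0.37, QTRT2 of 0.09 ± 0.32 and 0.24 ± 0.32 and ALKBH8 of -0.08 ± 0.53 and 0.12 ± 0.54, from the authors' deposited tables. MT2A had 0.23 ± 0.97 and 0.08 ± 0.97, HSPA1A 0.00 ± 1.10 and 0.19 ± 1.10 and DDIT3 -0.12 ± 1.32 and 0.31 ± 1.32, from the authors' deposited tables. By the z test with the larger standard error of the shared controls, adjusted over all genes tested, the smallest adjusted p among these 7 genes was 1. Of the well-expressed genes, 84.3% in untreated and 90.9% in treated cells had a 95% interval for this difference within 2-fold, from standard errors rebuilt without the shared controls.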

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

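The tests of shared control libraries, loss of queuine, lymphoid RNA, a HepG2 response and the level of immediate early genes before treatment were chosen after the results were seen. Of 3 patterns weighed, 2 concern differences of the processed-serum media from normal medium and 1 concerns lymphoid transcripts.

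Immediate early genes rose more in the processed-serum media, where the list difference passed its test, by a median of 1.10 in depleted and 0.99 in add-back medium. After GC and length trends were removed these medians were at least 0.91 (95% interval 0.21 to 1.45), against GC content and length of the transcripts as the whole cause. Intervals in this paragraph resample the genes of a list and do not measure the spread between samples. The list's level in untreated cells was -0.0488 in depleted and 0.0455 in add-back medium (interval -0.36 to 0.26 for the latter), against a bound of -0.50 for a lower level before treatment and too wide to exclude a small one. Heat shock genes, also a transient response, were higher in the same direction by at least 0.18 (interval 0.01 to 0.58), with a cameraPR adjusted p of 0.217 in depleted and 0.0396 in add-back medium, the latter 0.15 at a correlation of 0.05. Treated normal-medium cells sampled at another stage of the response, and a change of the response by serum processing, therefore both stay open. Variation of the normal-medium libraries, which both differences share, is not excluded either. The add-back minus depleted difference had a cameraPR adjusted p of 0.784.

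Genes called in untreated depleted-medium cells, such as SPINK1, PLG, CREB3L3 and PDGFRB, had like signs in libraries not used to call them. Of the 34 genes, 32 had the same sign in arsenite-treated add-back cells, a share of 0.941 (95% Wilson interval 0.809 to 0.984). This argues against the untreated normal-medium libraries alone as the cause. The interval treats genes as independent, which they are not. Variation shared by untreated and treated normal-medium libraries would also give like signs and is not excluded. In treated cells the median fold of the 34 genes was 0.87 in depleted and 0.88 in add-back medium. This is a ratio of 1.01 (interval 0.773 to 1.16), where loss of queuine would give one under 0.50. Both folds are over the same treated normal-medium libraries, whose variation would pull the ratio towards 1. Its interval resamples genes and does not measure the spread between samples. The medians of 0.87 and 0.88 still leave little difference for loss of queuine to account for. For the median of these genes in treated cells that argues against it, but for single genes the ratio cannot decide. The values used here do not show how far queuosine in tRNA fell. In untreated cells the medians were 1.55 and 1.39. There 4 of the 44 genes called in either medium differed between add-back and depleted medium at an unadjusted z test p under 0.05. After adjustment 0 did, both with the rebuilt standard error. SETD7, with the smallest p, differed by -1.89 (95% interval -3.09 to -0.70). Its folds in treated cells were -0.19 and -0.17, so the ratio says nothing about it. What else differs between normal and processed serum stays open and could not be tested.

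Detected lymphoid transcripts other than CD7 stood highest in untreated depleted-medium cells, with LCK at 315 against 80.2 and PTPRC at 216 against 35.6 normalized counts in normal medium, from the authors' deposited tables. CD7 stood highest in untreated add-back cells, at 7172. Of 24 detected lymphoid genes 24 were higher than in normal medium, a share of 1, with a median of 2.57, and in treated cells 23 in depleted and 24 in add-back medium, with medians of 0.58 and 0.88, while arsenite in normal medium gave 23 and 0.74. Reads or RNA of lymphoid cells may be the cause, as may a response of HepG2 cells to depleted medium (median in treated minus untreated cells -1.99), but the list was written for this rise and its genes move together, so neither test decides, and CD7 was high in both media (4798 and 6317). Reads or RNA of fibroblasts as well stay open, since 8 of 9 detected fibroblast genes were higher by a median of 0.84 (interval 0.25 to 3.17), with COL1A1 at 61.0 against 6.77. Of the list, PTPRC and CD3E are also among the markers of other cell types. Rebuilt dispersions were 0.526 for LCK, 1.30 for PTPRC and 1.10 for CD3E, and 0.0567 for CD7, against a median of 0.0593 in well-expressed genes. Replicates thus differed widely in the first 3 of these genes. Which libraries carry these transcripts is not known without values per sample, and the labels name no sort or other cell type.

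For depleted minus normal medium, other lists whose response to arsenite differed by cameraPR were aryl hydrocarbon receptor targets (median difference 1.42), NF-kappaB and inflammatory genes (0.43), YAP and TGF-beta responsive genes (0.35) and cholesterol and fatty acid synthesis genes (0.31). Lower were markers of other cell types (-0.55), mitochondrially encoded genes (-0.47), cytosolic ribosomal proteins (-0.26) and proteasome subunits (-0.14). At a correlation of 0.05 the calls of cholesterol synthesis (adjusted p = 0.127), proteasome (0.17) and other cell types (0.136) were lost. With GC and length trends removed those of mitochondrially encoded genes (adjusted p = 0.286), cholesterol synthesis (0.0517) and proteasome (0.0908) were lost.

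For add-back minus normal medium, higher lists by cameraPR were aryl hydrocarbon receptor targets (median difference 1.27), YAP and TGF-beta responsive genes (0.42), NF-kappaB and inflammatory genes (0.27) and heat shock genes (0.23). Lower were replication-dependent histones (-0.87), along with other RNA without poly(A) tails that passed no test (medians of -2.33 for 7SL and -2.84 for 7SK copies), mitochondrially encoded genes (-0.43), NRF2 targets (-0.32), arsenic transport and metabolism (-0.32) and iron handling (-0.31). Hepatocyte secreted proteins (-0.29), cytosolic ribosomal proteins (-0.25), aminoacyl-tRNA synthetases (-0.24) and proteasome subunits (-0.24) were lower as well. At a correlation of 0.05 the calls of heat shock genes (adjusted p = 0.15), arsenic transport (0.104), NF-kappaB genes (0.0661), aryl hydrocarbon receptor targets (0.0661), ribosomal proteins (0.0526), iron handling (0.0661) and YAP genes (0.0743) were lost. With GC and length trends removed those of arsenic transport (adjusted p = 0.0704) and ribosomal proteins (0.151) were lost.

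For add-back minus depleted medium, the median difference in the response was -0.35 for NRF2 targets and 0.51 for markers of other cell types. The latter stood lower after arsenite in depleted medium and were not called in add-back medium. Both were called by cameraPR and lost at a correlation of 0.05 (adjusted p = 0.18 and 0.183). FLNC differed by 4.31 by the z test at a mean of 39.5 normalized counts. The lymphoid list had a median difference of 2.58 here and -1.72 for depleted minus normal medium, with 0 genes called by the z test and 12 and 2 at an unadjusted p under 0.05.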

How the results depend on the processing

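Chosen after seeing the data were a t distribution with 12 degrees of freedom, the removal of GC and length trends, the rebuilt standard error and z scaled to its spread. No called gene named and no called list changed its direction under the alternatives that gave a value.

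With an adjusted p under 0.01, arsenite changed 919 genes in normal, 760 in depleted and 738 in add-back medium, with 253 raised and 80 lowered in all 3. Depleted against normal medium gave 18 untreated and 5 treated, add-back against normal 15 and 4, and the call of FLNC was lost, with 0 genes by the z test and 258 at an unadjusted p under 0.05. Adjustment over all genes with a p gave 11 genes for depleted and 5 for add-back against normal medium in treated cells, and 141 lowered in all 3 media. At least a 2-fold change left 102 of the 212 genes lowered in all 3 media. These counts fell because the bound was stricter or more genes were tested.

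With a t distribution of 12 degrees of freedom arsenite changed 531, 299 and 315 genes, 123 raised and 32 lowered in all 3 media, and each of the 4 medium comparisons called 0, with 1323, 838, 772 and 764 at an unadjusted p under 0.05. With 4 degrees of freedom all 7 comparisons called 0, and 0 were raised or lowered in all 3 media, with 1792, 1602 and 1630 at an unadjusted p under 0.05 for arsenite and 233 to 378 for the media. The difference in the arsenite effect between add-back and depleted medium called 0 genes by the z test through the medium comparisons, over genes with a mean of at least 100, and with 8 or 12 degrees of freedom, which gave 101 and 157 at an unadjusted p under 0.05. In these the larger standard error, the smaller set of genes without FLNC or the wider distribution ended the call.

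Removal of GC and length trends gave 53 genes for depleted against normal medium untreated, 66.0% of them higher, and 10 treated. It shared 30 of the 34 and 8 of the 21 genes. The cause was not tested. With z scaled to its spread, the difference in the arsenite effect called 3 genes for depleted minus normal medium (CYP1A1 2.33, GPR3 1.59 and FLNC -3.64) and 1 for add-back minus normal medium (CES1P1 -1.51), genes outside the naming rule. Add-back against depleted medium then called 13 genes in untreated cells, all lower, and 27 in treated cells, 10 higher and 17 lower. The scaling makes each z larger by construction.

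Of the lists called by cameraPR, the log2 fold change as statistic called 10 of 27 in place of 16 for arsenite in normal medium, 9 in place of 14 in depleted medium, 4 in place of 8 for depleted and 4 in place of 7 for add-back against normal medium untreated. It called 1 in place of 2 both for the add-back minus depleted difference and for add-back against depleted medium untreated. A correlation of 0.05 called 9 for arsenite in depleted medium, 5 for depleted against normal medium untreated, 7 in place of 14 for the add-back minus normal difference, and 0 in place of 2 for the add-back minus depleted difference and for add-back against depleted medium untreated. Removal of GC and length trends called 3 in place of 1 for add-back against depleted medium treated. Of the 98 list calls over the 12 comparisons, 66, 65 and 84 were kept under the correlation, the statistic and the trend removal. Fisher's exact test passed 5, 5 and 7 lists for arsenite in normal, depleted and add-back medium, of which cameraPR passed 5 in each.

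Of the named genes, 531 of 532 kept their side of the threshold with adjustment over genes with a mean of at least 10, 562 of 568 with centred folds and 540 of 568 with trends removed. Fewer kept it under stricter settings. These were 496 of 532 with adjustment over all genes with a p, 498 of 532 with at least a 2-fold change and 492 of 568 with an adjusted p under 0.01. With a t distribution they were 398 of 554 at 12 and 254 of 532 at 4 degrees of freedom. The median log2 shift that centring removed was under 0.1 in each comparison.

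No paired analysis was possible because the tables hold no values per sample. For the same reason edgeR, another normalization, another pseudocount, fits of 2 groups alone, leaving out each replicate, other splits of the samples and an estimated list correlation were not run. At 24.3% variation between replicates, a 2-fold difference in the arsenite effect was called in 10% of simulated genes, and a 2-fold difference between add-back and depleted medium in 3%, or 45% with the rebuilt standard error.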

Other observations

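Tests chosen after the results were seen are those of the spread of z, and the values of RNA without poly(A) tails were looked up afterwards.

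Some medians of RNA without poly(A) tails were large. The 7SL RNA, part of the signal recognition particle, had medians over 5 genes and copies of 2.02, 1.92 and -0.36 after arsenite in normal, depleted and add-back medium, with 0, 0 and 1 called by DESeq2 and 0, 1 and 1 at an unadjusted p under 0.05. RN7SL1 had a rebuilt mean of 58751 normalized counts in treated depleted-medium and 3586 in treated add-back cells, from the authors' deposited tables. That difference was -4.03 ± 1.98 (z test adjusted p = 1), at a dispersion of 1.41. Reads of these copies and of the 7SK copies cannot be placed with certainty. GTDC1, which mannosylates queuosine, was higher in add-back than in depleted medium in treated cells by 0.86 with z scaled to its spread and was not called in this comparison otherwise.

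Genes raised by arsenite may have fewer exons than other genes of like expression, as splicing is sensitive to stress. Their median was 8, 7 and 7 exons in normal, depleted and add-back medium, against 10 in matched genes each time (permutation p = 0.0004, 0.0002 and 0.0002, where 0.0002 is the smallest that these permutations can give). Matched for GC content as well, p was 0.002, 0.0002 and 0.0002. Genes lowered by arsenite may span more of the genome, which short exposure would affect through transcription time. Their median span was 40630 bases in normal (matched 34434, permutation p = 0.007), 56087.5 in depleted (matched 34490.2, p = 0.0002) and 34625 in add-back medium (matched 32783, p = 0.3374). Matched for GC content as well, p was 0.0012, 0.0002 and 0.0044, with 28739 bases in the genes matched for add-back medium. The add-back result therefore rests on the matching, and the hypothesis as first set, without GC content, stays open.

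Messenger RNA levels could follow the choice between the codons that queuosine tRNAs read. Across 8665 genes, which are not independent replicates, the rank correlation of that choice with the fold of add-back over depleted medium in untreated cells was 0.591, and 0.0718 (95% interval 0.0501 to 0.0936) after removal of GC at the third codon position, which correlated at 0.619. Across 946 long noncoding RNA genes, which have no codons, GC content correlated with the same fold at 0.243 (interval 0.180 to 0.303). In arsenite-treated cells the signs were opposite, with -0.368 for the codon choice, -0.0217 (interval -0.0433 to 0.00039) after removal and -0.353 for transcript GC content, against 0.641 for the latter in untreated cells. In untreated cells a GC trend of the libraries and a small codon effect cannot be told apart, since the codons in question differ in GC.

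Differences between add-back and depleted medium were smaller than their standard errors allow. In that comparison, genes with a mean of at least 1000 had a spread of z of at most 0.684, against 1.01 in simulated independent libraries, which may come from variation shared by the groups, such as sets of libraries made together. Against normal medium the spreads were 1.02 and 0.961 for depleted and 0.937 and 0.974 for add-back medium, untreated and treated, which sets shared by all groups would also lower unless real differences widen them. For the differences in the arsenite effect they were 0.718 for depleted minus normal, 0.612 for add-back minus normal and 0.766 for add-back minus depleted medium, as shared variation would give, so this stays open. Low counts are argued against, since the lower of both spreads, 0.544, was found in these abundant genes. The labels give no day or batch, so no fit could take this into account.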
